A study of Arabidopsis thaliana with 16 samples.

How the data were processed

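Small RNAs were sequenced from crude extracts of Arabidopsis thaliana Col-0 leaves and flowers that had been separated by size on a gel-filtration column. Per the labels, plants were grown for 4 weeks under 8 h of light at 21 °C and then moved to 16 h of light. Young leaves came from plants of 6 weeks, and young flowers and buds came from inflorescences that already carried immature siliques. RNA was taken from the unfractionated extract (input, 30 µg) and from 3 pools of column fractions. The high molecular weight pool (HMW) joined fractions 6 to 10, about 500 to 800 kDa, where most of the Argonaute proteins AGO1 and AGO2 ran. The low molecular weight pool (LMW) joined fractions 19 to 25, about 66 to 200 kDa, where most AGO4 ran. The unbound pool joined fractions 29 to 35, about 20 to 40 kDa, and is described by the labels as free of protein. The small RNA range was isolated on an 8% gel and made into libraries with an Illumina small RNA kit. Each of the 8 groups held 2 libraries, which the series describes as biological replicates.

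The submitters deposited a single table of 13752446 distinct sequences of 20 to 25 nt by 16 libraries. Their processing notes name cutadapt 1.9.1, Bowtie, SAMtools 1.3.1, bedtools 2.26.0 and the TAIR10 genome, without a role or order for each tool. The 4 HMW columns of the deposited table hold reads per 1000000 reads (RPM) and sum to 1000000 each. The other 12 deposited columns hold a signal whose column sums run from 496157 to 2154688. In all 16 columns the values were whole multiples, within 0.01 read, of 1 constant per library, so the reads behind each value could be recovered. In the 12 columns that hold the signal, the constant equalled 1000000 divided by the total of another library of the same tissue and replicate. The total of the unbound library set the input column, that of the input set LMW, and that of LMW set unbound.

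Whether the constants or the column labels were exchanged was checked on the 16578 tested sequences outside structural RNA and organelles. If the input is taken as a mixture of the pools, few sequences should exceed every pool by far in it. Sequences over 2 times the highest of the other 3 columns were fewest in the column labelled input in both replicates of both tissues. Their share was 1.48% and 3.04% in the leaf inputs and 3.84% and 6.77% in the flower inputs. The next lowest shares were 3.94% and 4.14% in leaf, both in HMW, and 5.47% and 6.85% in flower, both in LMW, so the margin in the second flower set was small. This check cannot settle the labels, since whole classes of the input lay outside the range of the pools. In leaf, rRNA made up 8.16% of input reads against 80.7% of HMW, 50.9% of LMW and 20.1% of unbound reads. MIR genes made up 14.3% against 8.31%, 2.85% and 4.25%. An exchange of the LMW and unbound labels was not tested. The labels were used as given, and each library was divided by its own recovered total. The values as deposited were kept as an alternative chosen after seeing the data.

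Library totals ran from 3204615 to 16876278 reads of 20 to 25 nt. At this depth a count of 0 allows up to 3 reads, which is 0.178 RPM in the deepest library and 0.936 RPM in the shallowest. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

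Every sequence was matched exactly, on both strands, to the TAIR10.1 assembly and its RefSeq annotation, the reference at hand. Of the sequences, 66.7% had a match. A sequence with matches in several annotation classes went to the first of MIR gene, trans-acting siRNA (TAS) locus, tRNA, rRNA, snRNA or snoRNA, plastid, mitochondrion, pseudogene and protein-coding gene. Sequences that matched elsewhere in the nuclear genome formed the class of unannotated nuclear genome. The annotation has no class for transposable elements. rRNA was extended over the 3600 nt that follow the 5.8S genes, which the annotation covers only in part. Mature miRNAs were matched by their exact sequence, never by gene symbol.

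Sequences with at least 10 RPM in at least 2 libraries were tested, which left 21915. Their log2(RPM + 1) values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 8 groups and empirical Bayes moderation with a trend, on 8 residual degrees of freedom. There were 11 contrasts. P-values were adjusted by Benjamini and Hochberg over all sequences of a contrast, with a threshold of 0.05. Shares of 24 classes of length and first base and of 11 annotation classes were fitted in the same way, as log2 of the percent of reads plus 0.01, and adjusted within each family. The star to guide ratio of 21 hairpins was log2 of (star RPM + 1) over (guide RPM + 1). Lists were tested with camera of limma at its preset correlation of 0.01 and again with an estimated correlation. The p-values measure the spread between these libraries alone. With 2 libraries against 2, an exact permutation test cannot go below p = 0.333. On simulated data with a dispersion of 0.1, set up as leaf HMW against unbound, limma recovered 7.46% of 2-fold, 50.7% of 4-fold and 90.9% of 8-fold changes, and it called 10 unchanged sequences among 21915. edgeR 4.0.16 recovered 2.99%, 47.8% and 90.9% and called 6. The common dispersion that edgeR estimated in the real libraries was higher, at 0.259. The simulation also gave all groups the same composition apart from the planted changes, so recovery in these data is likely lower. Other work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and the R package data.table (1.17.8).

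Comparisons, lists, the rule for named sequences and most alternative analyses were fixed before the data were examined. The lists held guide miRNAs and, among them, miRNAs of development, nutrient response, silencing factors, triggers of secondary siRNAs, young miRNA families and pollen. Star strands and trans-acting siRNAs formed lists of their own. The pollen list could not be tested, since 0 of its 2 members passed the filter on level. Named for each comparison were 11 fixed guides (miR156a, miR158a, miR159a, miR161.1, miR163, miR166a, miR168a, miR172a, miR173, miR390a and miR403) and the listed trans-acting siRNAs. Added to them were the 8 catalogued miRNAs, stars or trans-acting siRNAs with the largest positive and the 8 with the largest negative difference, and at most 3 other sequences of each sign. These additions needed an adjusted p under 0.05 and both libraries of one group above both of the other. Other members named in the text were chosen after their values were seen.

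Alternative analyses fixed in advance were a median-ratio scaling, a scaling without rRNA, tRNA, snRNA, snoRNA and organelle reads, other pseudocounts, other filters, no trend, only the compared groups, a replicate block, summed isoforms, single-match sequences, distinct sequences and leaving out each library. Added after seeing the data were the deposited scale, edgeR quasi-likelihood with and without TMM, class shares outside structural RNA and organelles, and the test of whether star to guide differences differ between tissues. The design had assumed lengths of 18 to 30 nt, and the table holds 20 to 25 nt only.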

Results

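The data comprised 16 small RNA libraries, 2 from each of 8 groups. The groups were leaf input, leaf HMW, leaf LMW, leaf unbound and their flower counterparts. The deepest library, a flower input, held 16876278 reads of 20 to 25 nt, and the shallowest, a leaf HMW library, held 3204615. Values are given as mean ± SD with n = 2 or as log2 differences ± SE from the limma fit. All values are shares of a library and not amounts per plant or per pool. Within groups, the log2 RPM of the tested sequences correlated between replicates with r from 0.864 in flower unbound to 0.956 in flower input, across sequences that are not independent of each other.

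The first question was which kinds of small RNA ran in each size range. In leaf, 24-nt sequences made up 53.0% ± 5.73 (SD, n = 2) of the input reads and 17.5% ± 1.57 (SD, n = 2) of HMW. They made up 46.1% ± 6.22 (SD, n = 2) of LMW and 43.3% ± 0.0475 (SD, n = 2) of the unbound pool. Flower had the same order for input and HMW, with 64.4% ± 4.67 (SD, n = 2) in the input and 26.8% and 35.2% in the HMW libraries. The unbound pools held the largest 23-nt shares, 29.7% ± 0.450 (SD, n = 2) in leaf and 40.6% and 44.9% in the flower libraries. The inputs held 17.7% and 18.3% in leaf and 17.6% ± 0.695 (SD, n = 2) in flower. Fragments of rRNA made up 80.7% ± 3.69 of leaf HMW and 63.1% ± 4.53 of flower HMW reads (SD, n = 2), and 8.16% ± 3.30 and 1.40% ± 0.170 of the inputs (SD, n = 2).

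**Figure D1:**
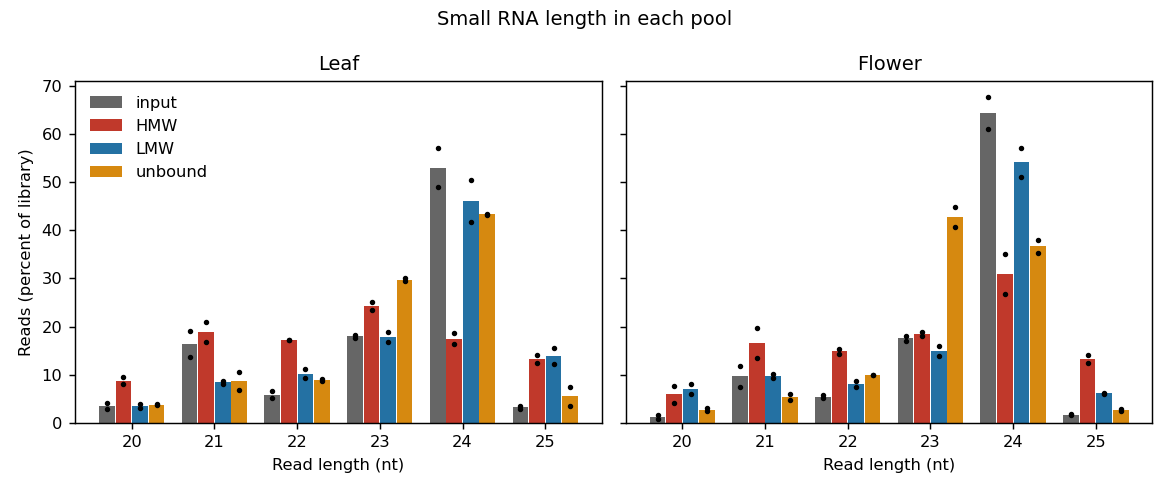
Bars give the mean percent of reads at each length from 20 to 25 nt in input, HMW, LMW and unbound libraries of leaf and flower, and points give the 2 libraries of each group. The 23-nt share of the unbound pools reached 29.7% in leaf and 42.8% in flower.

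Reads of 21 nt that began with U, the form favoured by AGO1, were enriched in HMW. Their share exceeded that of the unbound pool 2.90-fold in leaf (log2 1.54 ± 0.38, adjusted p = 0.00544) and 6.70-fold in flower (2.74 ± 0.38, adjusted p = 2.1e-05). Reads of MIR genes followed, 2.12-fold higher in leaf (1.08 ± 0.39, adjusted p = 0.0130) and 5.27-fold higher in flower (2.40 ± 0.39, adjusted p = 2.2e-05). Reads of 24 nt that began with A, the form favoured by AGO4, were 8.24-fold lower in HMW than in the unbound pool of leaf (-3.04 ± 0.32, adjusted p = 3.3e-06) and 2.08-fold lower in flower (-1.06 ± 0.32, adjusted p = 0.0107). Among reads outside structural RNA and organelles, the leaf difference was -1.59 ± 0.24 (adjusted p = 6.2e-05) and the flower difference turned to 0.08 ± 0.24 (adjusted p = 0.740). With distinct sequences counted once, the leaf call ended (-0.19, adjusted p = 0.223) and the flower share was higher in HMW (0.43, adjusted p = 0.0149). Reads of 23 nt that began with A were 3.20-fold lower in HMW than unbound in leaf (-1.68 ± 0.36, adjusted p = 0.00405) and 8.51-fold lower in flower (-3.09 ± 0.36, adjusted p = 1.1e-05). The 21-nt U and MIR gene calls in leaf ended when certain single libraries were left out, with values down to 0.93 and 0.39, and they also ended among sequences past the filter (0.61 and 0.13), as did the leaf 23-nt A call (-0.85). In flower, the 24-nt A call ended in leave-one-out fits as well, with values from -1.39 to -0.72.

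**Figure D2:**
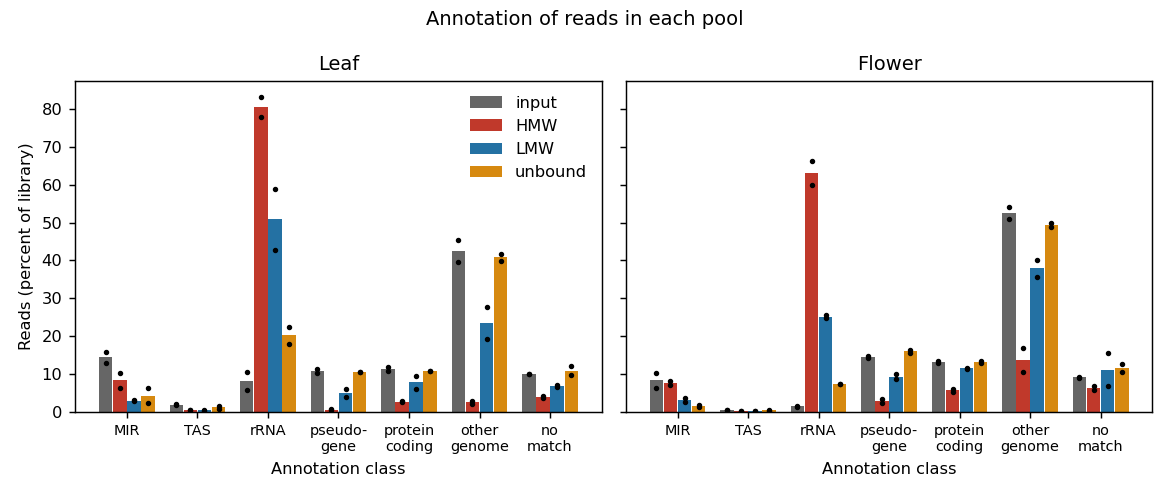
Bars give the mean percent of reads in each annotation class for input, HMW, LMW and unbound libraries of leaf and flower, and points give the 2 libraries of each group. The rRNA class took 80.7% of leaf HMW and 63.1% of flower HMW reads.

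The central comparison asked which miRNAs were enriched in the range of AGO1 and AGO2 complexes over the protein-free range. In leaf, most guide miRNAs were higher in HMW than in the unbound pool. The strongest were miR159a, which targets MYB factors (68.8-fold, log2 6.10 ± 0.68, adjusted p = 6.4e-06), and its relative miR159b-3p (5.35 ± 0.75). They rose with miR161.2, which targets pentatricopeptide repeat genes (5.13 ± 0.79), and miR165a-3p, a regulator of HD-ZIP III leaf polarity genes (3.96 ± 0.79). miR166a-3p, the most abundant of these, stood at 42414 ± 15396 RPM in HMW and 7951 ± 3370 RPM in the unbound pool (SD, n = 2), a log2 difference of 2.43 ± 0.56 (adjusted p = 0.00214). Of the 35 guides tested, 21 were higher, 1 was lower and 13 did not pass, and the same counts held when adjusted over the list alone. The guide at the median, miR162a-3p, which targets DCL1, was 3.72-fold higher; the list median log2 ran from 1.06 to 2.86 when single libraries were left out. The guide list was called by camera (adjusted p = 2.9e-11), but not with its estimated correlation (adjusted p = 0.275 with an estimated correlation).

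Among the smaller leaf lists, the development list had 7 of 14 members higher and 1 lower, with miR167d, a regulator of auxin response factors, at 3.86 ± 0.93 (camera adjusted p = 3.5e-05; adjusted p = 0.276 with an estimated correlation). The young families had 9 of 12 higher, among them miR158a-3p (2.71 ± 0.64) and miR163 (2.82 ± 0.72) (camera adjusted p = 1.4e-06; adjusted p = 0.275 with an estimated correlation). The nutrient list had 2 of 4 higher, with miR408-3p, which targets copper proteins, at 3.47 ± 0.79 (camera adjusted p = 0.00290; adjusted p = 0.275 with an estimated correlation). Among silencing factors 2 of 3 were higher, miR403-3p, which targets AGO2 (2.55 ± 0.56), and miR162a-3p (adjusted p = 0.0184). The third, miR168a-5p, which targets AGO1, was at -1.03 ± 0.67 (adjusted p = 0.244); this list had camera adjusted p = 0.0464 and adjusted p = 0.281 with an estimated correlation. All 3 trans-acting siRNAs were higher, namely siR480 (2.04 ± 0.59), siR255 (1.72 ± 0.37) and tasiR-ARF-D7, which targets auxin response factors (2.90 ± 0.59) (camera adjusted p = 0.00259; adjusted p = 0.275 with an estimated correlation). In the trigger list miR173-5p, which starts TAS1 and TAS2 siRNAs, rose (1.21 ± 0.44) and miR390a-5p, which starts TAS3 siRNAs, was at -0.90 ± 0.76 (adjusted p = 0.391); that list was not called (camera adjusted p = 0.230). For every list these counts were the same when adjusted over the list alone. Values of single guides depended on the exact sequence: with isoforms within 2 nt summed, miR167d went to 0.14, miR173-5p to -0.61 and miR159a to 3.94, and camera no longer called the silencing list.

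Some leaf guides were not enriched in HMW. miR156a-5p, which targets SPL phase-change genes, was at -1.20 ± 0.69 (adjusted p = 0.176), and miR161.1 was at 1.33 ± 0.75 (adjusted p = 0.167). With isoforms within 2 nt summed, miR156a-5p went to -2.72 and miR168a-5p to -2.33, while miR161.1 was at 1.43. miR172a, which targets AP2 genes and was scarce (3.35 RPM in HMW, 8.39 RPM unbound), was lower in HMW (-1.11 ± 0.38, adjusted p = 0.0246). That call ended and its sign turned without structural RNA reads (0.74), with median-ratio scaling (0.42) and in edgeR (0.04). The rRNA share of leaf HMW, 80.7%, weighs on every such value. Without structural RNA and organelle reads, 28 guides were higher and 0 were lower, with a median of 4.02.

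Star strands, listed as the passenger strands of miRNA duplexes, went the other way in leaf. The list held 24 stars, and 13 of them passed the filter on level. Of these 13, 12 were lower in HMW than in the unbound pool and 0 were higher. The median log2 was -4.36, or -5.39 to -2.88 when single libraries were left out. A star can pass the filter through the unbound libraries where it is high, so the tested set may favour lower values in HMW. The same limit holds for the stars in the other comparisons. miR168a-3p was at 2.38 RPM in HMW and 205 RPM in the unbound pool (62.5-fold, -5.97 ± 0.70, adjusted p = 8.9e-06). miR396a-3p (-5.35 ± 0.71), miR167a-3p (-5.27 ± 0.56), miR824-3p (-5.13 ± 0.76) and miR166a-5p (-4.82 ± 0.73) were lower as well. So were the passenger-arm sequences miR156d-3p (-6.57 ± 0.61), miR157c-3p (-5.44 ± 0.62) and miR168b-3p (-5.28 ± 0.59). The star list was called by camera (adjusted p = 0.00434), though not with an estimated correlation (adjusted p = 0.291 with an estimated correlation); 12 were also lower when adjusted over the list alone. Without structural RNA reads, 9 stars were lower and the median was -2.94.

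Over all sequences, 11453 of 21915 differed between leaf HMW and unbound, 1766 higher and 9687 lower in HMW. The 4791 rRNA sequences and the 10606 of the unannotated nuclear genome parted: 1152 rRNA sequences were higher and 186 lower, against 33 higher and 6076 lower. The largest rise among sequences with a match was a 22-nt sequence of the rRNA class (chromosome 2, 5945 to 5966), at 444 RPM in HMW and 1.11 RPM in the unbound pool (7.75 ± 0.50). It overlaps only the edge of the 5.8S rRNA gene AT2G01020 and lies mostly in the stretch that follows that gene. The largest fall was a 20-nt sequence of MIR393b (chromosome 3, 20691778 to 20691797), at 1.40 and 353 RPM (-7.32 ± 0.61). The median of all sequences was -0.65, and it moved to -0.18 without structural RNA reads and to -0.11 with median ratios. These scalings gave 4786 higher with 7655 lower, and 4514 higher with 7563 lower.

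In flower HMW, guides again stood above the unbound pool. miR159a was 25.4-fold higher (4.67 ± 0.68, adjusted p = 5.7e-05), and miR398b-3p, which targets copper superoxide dismutases, was 22.5-fold higher (4.49 ± 0.94, adjusted p = 0.00101). miR159b-3p (4.45 ± 0.75), miR165a-3p (4.22 ± 0.79), miR166a-3p (4.00 ± 0.56), miR408-3p (3.71 ± 0.79) and miR403-3p (3.57 ± 0.56) were also higher. With isoforms within 2 nt summed, miR159a went to 3.10 and miR159b-3p to 2.65, while miR398b-3p was at 4.28. The annotated miR780.2 reached 477 ± 17.6 RPM in flower HMW and 17.3 ± 7.36 RPM in flower unbound (SD, n = 2; 4.77 ± 0.83, adjusted p = 0.000252). Of 35 guides, 21 were higher, 0 lower and 14 not called, with a median of 1.74, and as many when adjusted over the list alone. Camera called the list (adjusted p = 1.6e-06), but not with an estimated correlation (adjusted p = 0.473 with an estimated correlation). Without structural RNA reads 31 were higher.

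By list in flower, 8 of 14 development guides were higher and 0 lower (camera adjusted p = 0.000941; adjusted p = 0.473 with an estimated correlation), a call that ended with isoforms within 2 nt summed, where miR167d went from 2.18 to -1.56. Of 12 young families 7 were higher, with miR161.1 at 3.05 ± 0.75, miR163 at 2.98 ± 0.72 and miR158a-3p at 2.00 ± 0.64 (camera adjusted p = 0.00196; adjusted p = 0.473 with an estimated correlation). The nutrient list, with 3 of 4 higher, was not called (camera adjusted p = 0.0691), nor was the silencing list, with 2 of 3 higher (camera adjusted p = 0.123). siR255 was higher (0.95 ± 0.37, adjusted p = 0.0346), while siR480 (1.01 ± 0.59, adjusted p = 0.141) and tasiR-ARF-D7 (0.97 ± 0.59, adjusted p = 0.154) did not pass; no trans-acting siRNA passed when adjusted over the list alone. miR173-5p was higher (1.07 ± 0.44, adjusted p = 0.0432), and 0 of the 2 triggers passed when adjusted over the list alone. miR156a-5p (0.51 ± 0.69), miR168a-5p (0.43 ± 0.67), miR390a-5p (-0.13 ± 0.76) and miR172a (-0.26 ± 0.38) did not pass. Of 13 stars, 5 were lower and 1 higher, and camera did not call the list (adjusted p = 0.826). Without structural RNA reads 1 was lower and 2 were higher. The lower stars included miR165a-5p (-2.83 ± 0.92), miR168a-3p (-2.60 ± 0.70), miR396a-3p (-2.21 ± 0.71) and miR396b-3p (-2.08 ± 0.55). The star that rose was miR158a-5p (2.56 ± 0.62), at 13.5 RPM in HMW and 1.58 RPM in the unbound pool.

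Over all sequences in flower, 15237 differed, 5634 higher and 9603 lower in HMW. The 22-nt sequence at 5945 to 5966 on chromosome 2 was again among the largest rises, at 347 and 0.143 RPM, the latter below the limit that a count of 0 allows in those libraries. A 23-nt sequence on chromosome 5 (19726416 to 19726438), 234 nt from AT5G48650, was at 0.190 RPM in HMW and 195 RPM in the unbound pool. The median of all sequences was -0.75, and it was 0.01 without structural RNA reads, where 7856 were higher and 6664 lower.

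**Figure D3:**
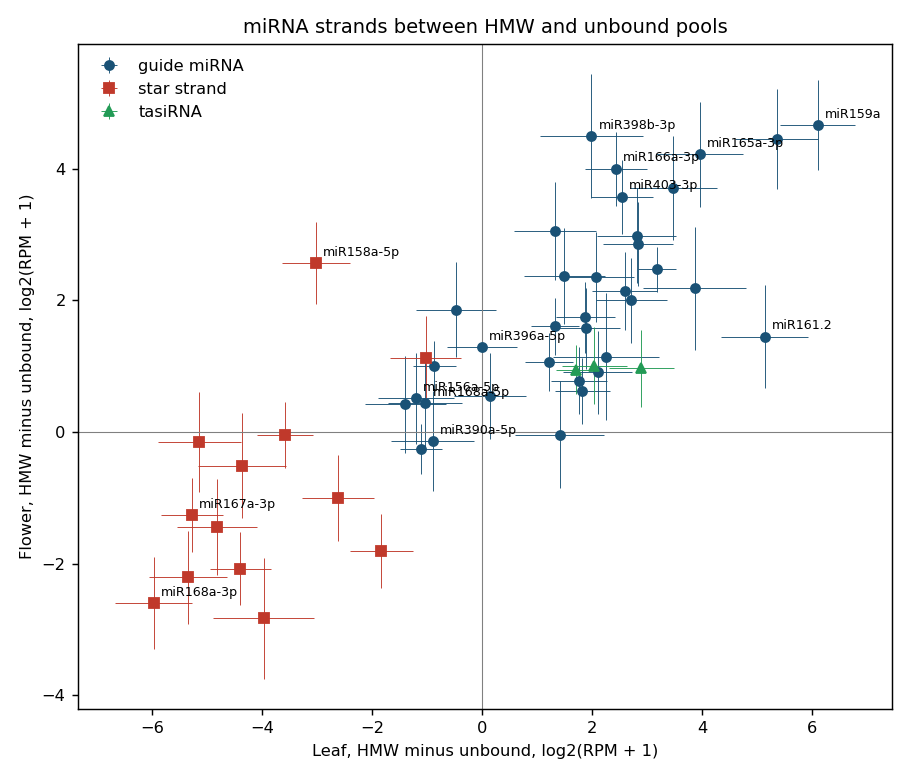
Points give the log2(RPM + 1) difference of HMW minus unbound in leaf (horizontal axis) and flower (vertical axis) for 35 guides, 13 stars and 3 trans-acting siRNAs, with bars of 1 SE. Of the guides 29 had the same sign in both tissues, and miR158a-5p lay below 0 in leaf (-3.02) and above 0 in flower (2.56).

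The star to guide ratio compares a listed star and a listed guide sequence within a library. The annotation held 428 mature miRNAs with 350 distinct sequences, so reads of a guide may come from several loci. For miR172a and miR393a-5p the listed star, miR172b-5p or miR393b-3p, is that of a related locus. A listed star was not always the rarer strand. Even in leaf HMW it exceeded its guide for MIR393 (25.6 against 1.24 RPM) and MIR824 (6.08 against 2.18 RPM). In leaf, 18 of 21 hairpins had a higher ratio in the unbound pool than in HMW and 0 a lower one, with a median log2 difference of 3.82. The largest were MIR165 (7.92 ± 0.99), MIR166 (7.25 ± 0.71), MIR167a (6.76 ± 0.56) and MIR158a (5.73 ± 0.78, adjusted p = 3.5e-06). MIR156 (-1.20 ± 0.65, adjusted p = 0.0896), MIR390a (0.84 ± 0.61, adjusted p = 0.198) and MIR172a (0.73 ± 0.55, adjusted p = 0.205) did not pass. The listed star of MIR156 was at 0 RPM in leaf HMW and leaf unbound, so its ratio followed the guide alone. In flower, 12 of 21 were higher and 0 lower, with a median of 1.73, among them MIR165 (7.05 ± 0.99), MIR398b (6.31 ± 0.73) and MIR166 (5.45 ± 0.71). The test of the difference between tissues, chosen after seeing the data, called 4 hairpins, all with less change in flower: MIR158a (-6.29 ± 1.10, adjusted p = 0.000488), MIR167a (-3.13 ± 0.80), MIR824 (-3.12 ± 0.91) and MIR171b (-2.91 ± 0.77). Where the star is near 0, the ratio follows the guide alone. Of the hairpins whose star reached 5 RPM in either pool, 13 of 13 in leaf and 7 of 10 in flower were higher in the unbound pool. In leaf each of these stars reached 5 RPM in the unbound pool, so the cut favours that pool. Among the 7 in flower, the stars of MIR408 (1.48 RPM unbound, 5.37 RPM HMW) and MIR171a (2.79 and 7.23 RPM) were lower in the unbound pool. Their ratios rose with the fall of the guide. The stars of MIR165, MIR166, MIR168, MIR396a and MIR396b were higher there.

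The difference between the tissues was then tested itself, as the flower minus leaf difference of HMW versus unbound. Of 13 stars, 9 had a higher value in flower and 0 a lower one (10 when adjusted over the list alone), with a median of 3.36. Only 4 were higher without structural RNA reads, with a median of 2.57. miR158a-5p (5.58 ± 0.88, adjusted p = 0.000473), miR824-3p (4.98 ± 1.07), miR167a-3p (4.00 ± 0.80) and miR171b-5p (3.53 ± 0.72) led them. Of 35 guides, only miR824-5p (1.86 ± 0.55) and miR161.2 (-3.69 ± 1.11, adjusted p = 0.0261) passed, and 0 when adjusted over the list alone. miR841a-5p (-2.49 ± 0.60) and miR847 (-2.82 ± 0.61) passed too; the sign of miR841a-5p reversed in edgeR with and without TMM, and that of miR847 without TMM only. Over all sequences limma called 6665, 4190 higher and 2475 lower in flower. edgeR with TMM called 0, with 1597 at an unadjusted p under 0.05, and without TMM it called 403, so this count rests on the tool. With median-ratio scaling the split turned to 1210 higher and 3996 lower, as the median of all sequences went from 0.87 to -0.31.

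HMW was next set against LMW, the range of most AGO4. In leaf, guides were higher in HMW for 34 of 35 members, with a median of 2.89, and all 35 when adjusted over the list alone. miR159a (36.3-fold, 5.18 ± 0.68, adjusted p = 5.0e-05), miR161.2 (5.13 ± 0.79), miR167d (4.89 ± 0.93), miR408-3p (4.77 ± 0.79), miR167a-5p (4.61 ± 0.73) and miR399b, which targets the PHO2 phosphate regulator (4.37 ± 0.60), led. miR168a-5p (2.45 ± 0.67), miR156a-5p (3.34 ± 0.69), miR390a-5p (2.80 ± 0.76) and miR172a (1.77 ± 0.38) were higher as well, and miR166a-3p did not pass (1.28 ± 0.56, adjusted p = 0.103). Camera called the guide list (adjusted p = 4.5e-32; adjusted p = 0.0414 with an estimated correlation). The development, nutrient, silencing, young and trans-acting siRNA lists were called with both correlations, with 13 of 14, 4 of 4, 3 of 3, 12 of 12 and 3 of 3 members higher. When adjusted over the list alone, all 14 development guides were higher and the other counts stayed. The trigger list, with 2 of 2 higher, was called by camera alone (adjusted p = 0.00330; adjusted p = 0.0574 with an estimated correlation). Of 13 stars 0 passed, with 0 also when adjusted over the list alone and a median of 0.03 (3 higher and a median of 1.34 without structural RNA reads); camera called them relative to other sequences (adjusted p = 0.0161; adjusted p = 0.345 with an estimated correlation).

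In flower, 13 of 35 guides were higher in HMW than in LMW and 0 lower (12 when adjusted over the list alone), with a median of 1.34; leaving out structural RNA reads gave 26 higher and a median of 2.35. They included miR161.1 (3.17 ± 0.75), miR159a (3.01 ± 0.68), miR408-3p (2.88 ± 0.79), miR403-3p (2.74 ± 0.56), miR168a-5p (1.77 ± 0.67) and miR173-5p (1.34 ± 0.44). Camera called the list (adjusted p = 1.3e-10; adjusted p = 0.278 with an estimated correlation). Of the smaller lists, development (4 of 14 higher), nutrient (2 of 4), silencing (3 of 3) and young (3 of 12) were called by camera, with adjusted p of 2.3e-05, 0.0235, 0.00760 and 7.8e-05, and none with an estimated correlation, where each adjusted p was 0.278 or 0.282. When adjusted over the list alone, young had 2 members higher and the other 3 of these lists kept their counts. Leaving out structural RNA reads gave 12 development and 7 young members higher. Trans-acting siRNAs (0 of 3) and triggers (1 of 2) were not called (camera adjusted p = 0.0612 for both). The stars miR168a-3p (-1.87 ± 0.70) and miR167a-3p (-1.49 ± 0.56) were lower in HMW (0 stars when adjusted over the list alone), as was miR780.1 (-1.74 ± 0.46). No star was lower and 2 were higher without structural RNA reads.

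Reads of 24 nt that began with A were 10.4-fold lower in HMW than in LMW of leaf (-3.38 ± 0.32, adjusted p = 8.7e-07) and 3.91-fold lower in flower (-1.97 ± 0.32, adjusted p = 0.000385). Over all sequences, 7782 differed in leaf, 648 higher and 7134 lower in HMW, and 12518 in flower, 2025 higher and 10493 lower. Of the 24-nt sequences tested, 44 were higher and 5943 lower in leaf, and 903 higher and 7879 lower in flower. With median ratios the medians of all sequences moved from -0.50 to 0 in leaf and from -0.99 to -0.44 in flower, and the splits became 3124 higher with 3392 lower and 4427 higher with 6496 lower. On the deposited scale the flower count fell to 5005, with 2586 higher and 2419 lower.

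LMW against unbound asked what set the AGO4 range apart from free RNA. In leaf, all 13 stars were lower in LMW, with a median of -4.05, and as many when adjusted over the list alone. They included miR168a-3p (-6.17 ± 0.70, adjusted p = 1.9e-05), miR824-3p (-5.17 ± 0.76) and miR167a-3p (-4.92 ± 0.56). Of 35 leaf guides, 12 were lower and 0 higher (13 and 1 when adjusted over the list alone), among them miR156a-5p (-4.54 ± 0.69), miR390a-5p (-3.70 ± 0.76), miR168a-5p (-3.48 ± 0.67) and miR172a (-2.88 ± 0.38). In flower, 4 guides were higher and 0 lower (2 when adjusted over the list alone): miR398b-3p (3.65 ± 0.94), miR165a-3p (2.59 ± 0.79), miR166a-3p (2.31 ± 0.56) and miR159b-3p (2.10 ± 0.75). The flower stars miR396a-3p (-2.24 ± 0.71) and miR396b-3p (-1.94 ± 0.55) were lower. Reads of 23 nt that began with A were lower in LMW than unbound, 2.69-fold in leaf (-1.43 ± 0.36, adjusted p = 0.0105) and 3.36-fold in flower (-1.75 ± 0.36, adjusted p = 0.00183). Reads of 24 nt that began with A did not pass in leaf (0.33 ± 0.32, adjusted p = 0.621) and were higher in LMW of flower (0.91 ± 0.32, adjusted p = 0.0276), where 21-nt U reads were higher too (1.66 ± 0.38, adjusted p = 0.00287). That 21-nt U call ended among sequences past the filter (1.16, adjusted p = 0.0555). The flower 24-nt A call ended among sequences past the filter (0.14) and in 4 of 4 leave-one-out fits. In leaf the 24-nt A share was higher in LMW outside structural RNA and organelles (1.07, adjusted p = 0.00210), and it also passed with distinct sequences counted once (1.14). The leaf 23-nt A call was lost in 3 of 4 leave-one-out fits and among sequences past the filter (-0.66). Counts of sequences were 6819 in leaf, 2303 higher and 4516 lower, and 10628 in flower, 5900 higher and 4728 lower. Leaving out structural RNA and organelle reads turned the leaf split to 4744 higher and 3748 lower. With only the leaf groups compared in the fit the leaf count was 51, and on median ratios the flower split was 1562 higher and 6687 lower, the median of all sequences moving from 0.58 to -0.20.

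Flower and leaf were compared within each pool. In the inputs, flower had less of miR841a-5p (-7.41 ± 0.42, adjusted p = 1.0e-07), miR167d (-6.33 ± 0.93), miR157a-5p, a relative of miR156 (57.0-fold, -5.83 ± 0.74), and miR156a-5p (-3.72 ± 0.69), and more of miR780.2 (6.45 ± 0.83), miR780.1 (4.71 ± 0.46), miR839-5p (3.73 ± 0.42), miR851-5p (3.04 ± 0.30) and miR397b (2.45 ± 0.47). Of 35 guides, 17 were lower and miR158b alone was higher (1.84 ± 0.43), with the same counts when adjusted over the list alone and a median of -1.65. Camera called the guide list (adjusted p = 0.00197; adjusted p = 0.571 with an estimated correlation). Development (6 of 14 lower, camera adjusted p = 0.0432) and young (8 of 12 lower, 1 higher, camera adjusted p = 0.0119) were called as well, and neither was with an estimated correlation (adjusted p = 0.571). All 3 trans-acting siRNAs were lower, with siR255 at -2.49 ± 0.37, without a call of the list (camera adjusted p = 0.0849). Nutrient (1 of 4 lower), silencing (1 of 3) and trigger (1 of 2) were not called. When adjusted over the list alone, silencing had 0 lower, trigger had 2, and the other lists kept their counts. Of 13 stars 10 were lower, and 11 when adjusted over the list alone, among them miR157a-3p (-5.26 ± 0.80) (camera adjusted p = 0.00346; adjusted p = 0.571 with an estimated correlation). rRNA made up 1.40% of flower and 8.16% of leaf input reads (-2.48 ± 0.29, adjusted p = 6.2e-07). In all, 12408 sequences differed, 6546 higher and 5862 lower in flower, and on median ratios 7906 were higher and 977 lower as the median of all sequences moved from -0.59 to 0.35.

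In HMW, flower was lower than leaf for 11 of 35 guides and higher for 2, miR319a, which targets TCP growth regulators (2.72 ± 0.96, adjusted p = 0.0460), and miR158b (1.75 ± 0.43); 12 were lower and 2 higher when adjusted over the list alone. Without structural RNA reads 22 guides were lower and the calls of miR319a and miR158b ended. The lower ones included miR167d (-5.63 ± 0.93), miR169h (-5.10 ± 0.81), miR157a-5p (-3.79 ± 0.74), miR161.2 (-3.27 ± 0.79) and miR158a-3p (-2.05 ± 0.64). In LMW, 6 guides were higher in flower, led by miR319a (6.01 ± 0.96, adjusted p = 0.000134), and 2 were lower, miR157a-5p (-2.89 ± 0.74) and miR167d (-2.73 ± 0.93); 6 and 1 passed when adjusted over the list alone. Without structural RNA reads the balance turned, with 5 higher and 7 lower. In the unbound pool, flower had 10 of 13 stars lower (11 when adjusted over the list alone), among them miR396a-3p (-4.70 ± 0.71), miR167a-3p (-4.51 ± 0.56) and miR168a-3p (-3.85 ± 0.70, adjusted p = 0.000406). It also had 15 guides lower (13 when adjusted over the list alone), such as miR157a-5p (-5.60 ± 0.74) and miR156a-5p (-3.63 ± 0.69), and 2 higher, miR319a (3.84 ± 0.96) and miR158b (1.47 ± 0.43). miR166a-3p was lower in flower (-1.40 ± 0.56), but was at 0.05 with median ratios. Sequences that differed numbered 6879 in HMW (6156 higher, 723 lower in flower), 11898 in LMW (7763 and 4135) and 13356 in the unbound pool (7101 and 6255). Median ratios gave 6320 higher with 1404 lower in HMW, 8062 higher with 1841 lower in LMW and 9193 higher with 1353 lower in the unbound pool. Without structural RNA and organelle reads, HMW had 6406 higher and 2552 lower.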

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

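These tests and the star to guide test between tissues were read after the results of both tissues were known; the latter was chosen after seeing the data. The HMW versus unbound difference was not the same in leaf and flower for 6665 of 21915 sequences by limma, although leaf and flower HMW were collected from the same column fractions. The count was 0 in edgeR with TMM and 403 without it, so it is a result of the tool as much as of the tissues.

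Among catalogued small RNAs, 20 differed between the tissues in this way by limma, and 0 did in edgeR with TMM. Passenger strands made up most of those with a higher value in flower. Of the 13 listed stars, 10 were lower in flower than in leaf unbound (median -3.44). In HMW 1 was higher and 0 were lower (median -0.49), but without structural RNA reads 0 were higher and 5 lower (median -1.52). The strands were miR158a-5p (5.58), miR824-3p (4.98), miR168b-3p (4.42), miR167a-3p (4.00), miR157a-3p (3.85), miR171b-5p (3.53), miR166a-5p (3.37), miR168a-3p (3.36), miR396a-3p (3.14), miR157c-3p (3.06), miR156d-3p (2.68) and miR396b-3p (2.32). Some of them were scarce in flower unbound, where the added 1 RPM limits any fall. miR167a-3p was at 2.36 RPM there against 70.2 RPM in leaf unbound, and miR158a-5p at 1.58 against 32.1 RPM. miR824-3p and miR168a-3p were less scarce there, at 14.8 and 13.3 RPM. miR780.2 (4.77) and miR780.1 (2.46) were near 0 in leaf, so their tissue difference is a flower difference alone. miR157d (2.82), miR824-5p (1.86) and miR851-5p (1.83) were higher too. miR161.2 (-3.69), miR847 (-2.82) and miR841a-5p (-2.49) had lower values in flower. The star to guide ratio differed between tissues for 4 hairpins, MIR158a, MIR167a, MIR824 and MIR171b. Scaling does not fully cancel in that ratio where a strand is near 1 RPM, as the guide of MIR824 and the star of MIR167a were in some pools.

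Of the read shares, 24-nt A (1.98), 24-nt C (1.37) and 25-nt C (1.69) had a higher HMW versus unbound difference in flower, and 23-nt G (-1.19) a lower one. The unannotated nuclear genome (2.21) and pseudogenes (2.00) were also less reduced in flower HMW than in leaf HMW. rRNA took 80.7% of leaf HMW and 63.1% of flower HMW reads, which leaves other classes less room in leaf. That room accounts for little of the 24-nt A difference, since the tissues still differed by 1.67 (adjusted p = 0.00177) outside structural RNA and organelles. The unannotated genome still differed there by 1.44 (adjusted p = 0.000583), whereas 25-nt C, at 0.42, no longer passed.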

How the results depend on the processing

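The sign of some named miRNAs changed with the scaling or with the tool. With median ratios, miR172a in leaf HMW versus unbound went to 0.42 and miR166a-3p in flower versus leaf unbound to 0.0499. Without structural RNA and organelle reads miR172a was at 0.74, and in edgeR at 0.0389. In the tissue difference of HMW versus unbound, miR841a-5p turned to 1.36 in edgeR and 2.37 in edgeR without TMM, and miR847 to 0.67 without TMM. The cause was not tested.

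A filter of 50 RPM tested fewer sequences and gave fewer calls: 1776 and 2984 for HMW versus unbound in leaf and flower, 1262 and 1889 for HMW versus LMW, 1071 and 1749 for LMW versus unbound. Flower versus leaf gave 1974 in input, 1471 in HMW, 1846 in LMW and 2054 in unbound, and the tissue difference 705. Without a filter 4267558 sequences were tested, which gave 185490 and 423854, 27492 and 82676, 165049 and 389227, then 475920, 37620, 90094 and 428112, and 215114 for the tissue difference. A pseudocount of 0.1 gave 3808 for the tissue difference. With only the compared groups, leaf HMW versus LMW had 3793 calls and leaf LMW versus unbound 51. As deposited, HMW versus LMW had 4439 in leaf and 5005 in flower, flower LMW versus unbound 5717, the inputs 7861 and the tissue difference 3497. edgeR gave 6367 for flower LMW versus unbound and 0 for the tissue difference, or 403 without TMM. The lengths of 20 to 25 nt alone were to be an alternative, but the table holds no others.

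Among sequences past the filter, the 21-nt U share was 0.61 (leaf HMW versus unbound), 1.15 and 0.71 (HMW versus LMW, leaf and flower) and 1.16 (flower LMW versus unbound). The 23-nt A share was -0.85 (leaf HMW versus unbound), -0.43 (flower HMW versus LMW) and -0.66 (leaf LMW versus unbound), and 24-nt A 0.14 (flower LMW versus unbound). MIR genes were at 0.13 (leaf HMW versus unbound), 0.87 (flower HMW versus LMW), -1.04 and 0.41 (LMW versus unbound), and rRNA at 0.30 (leaf HMW versus LMW) and 0.68 (leaf LMW versus unbound). With each distinct sequence counted once, 24-nt A was at -0.19 in leaf and 0.43 in flower HMW versus unbound, and 1.14 in leaf LMW versus unbound, the last 2 of which passed; 23-nt A was at -0.34 in leaf HMW versus LMW. The unannotated genome was at -0.32 and -0.13 in flower HMW versus unbound and LMW and -0.28 in leaf LMW versus unbound, and MIR genes at 0.0667 (flower HMW versus LMW) and 0.30 (flower LMW versus unbound). Outside structural RNA, 24-nt A was at 0.0817 in flower HMW versus unbound and 1.07 in leaf LMW versus unbound, 23-nt A at -0.65 in leaf HMW versus LMW, the unannotated genome at -0.0426 in leaf LMW versus unbound and MIR genes at 1.38 in flower LMW versus unbound. Among sequences with 1 genomic match, MIR genes were at -1.01 in leaf and 0.0819 in flower and the leaf unannotated genome at -0.16, all LMW versus unbound.

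With an estimated correlation camera lost the guide lists of leaf and flower HMW versus unbound (1.895 and 1.74), flower HMW versus LMW (1.34) and input (-1.65), and the star lists of leaf HMW versus unbound (-4.36), leaf HMW versus LMW (0.0350) and input (-2.13).

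Leaving out single libraries, with the lone sample assumed to vary like the other groups, moved some calls. The tissue difference had 4224 to 5963 calls. For HMW versus unbound, 21-nt U in leaf ran from 0.93 to 2.14, 24-nt A in flower from -1.39 to -0.72 and MIR genes in leaf from 0.39 to 1.77. For HMW versus LMW, 21-nt U ran from 1.23 to 1.76 in leaf and 0.967 to 1.205 in flower, 23-nt A in flower from -1.42 to -1.25, MIR genes in flower from 1.09 to 1.60, rRNA in leaf from 0.45 to 0.91 and the leaf star list from -0.69 to 0.58. For LMW versus unbound, 23-nt A in leaf ran from -1.96 to -0.90, 24-nt A in flower from 0.80 to 1.02, MIR genes from -1.11 to 0.27 in leaf and 0.80 to 1.31 in flower, and the unannotated genome in leaf from -1.08 to -0.55.

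A replicate block gave 11861 calls for leaf HMW versus unbound, sequences, of which 11377 were shared, and the 57 main results run with it kept their answer. Among other values the block made 6 stronger and 1 weaker, with 308 the same. Within a tissue, correlations of the differences between replicates of paired groups ran from -0.12 to 0.48.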

Other observations

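Certain sequences were found mostly in the LMW pool. A 24-nt sequence with 2 exact matches in the genome reached 7701 ± 913 RPM in leaf LMW (SD, n = 2). The match listed first lies between the glucose-6-phosphate dehydrogenase gene G6PD2 and Pnsl5 (chromosome 5, 4162131 to 4162154). The sequence stood at 13.2 RPM in leaf input, 6.29 RPM in leaf HMW and 51.4 RPM in leaf unbound (HMW versus LMW -10.04 ± 0.53, adjusted p = 3.0e-07). Flower LMW held 2649 ± 350 RPM of it and 5073 ± 1404 RPM of the 20-nt form with the same start (SD, n = 2). A 25-nt sequence beside HVA22H (chromosome 1, 6926864 to 6926888) was also highest there, at 2517 ± 493 RPM in leaf LMW and 2784 ± 477 RPM in flower LMW (SD, n = 2). Its leaf HMW versus LMW difference was -7.21 ± 0.57 (limma adjusted p = 4.9e-06). The 21-nt form of that locus was not limited to LMW in leaf, with 256.1 RPM in LMW, 254 RPM in the unbound pool and 372 RPM in the input. Some 24-nt loci were abundant in flower alone. A sequence 2128 nt from MIR167d (chromosome 1, 11140043 to 11140066) was at 2363 RPM in flower LMW and 0 in leaf LMW. It overlaps the edge of AT1G06417, with its midpoint outside that gene.

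Smaller read classes parted as well. Reads of TAS loci as a whole were lower in HMW than in the unbound pool (leaf -1.27, adjusted p = 0.00142; flower -1.21, adjusted p = 0.00302), although siR255 was higher in HMW of both tissues. The direction rested on rRNA: outside structural RNA and organelles the TAS difference was 0.82 in leaf (adjusted p = 0.0353) and 0.0711 in flower (adjusted p = 1.00). Of the 182 tested TAS sequences in leaf, 42 were higher and 109 lower. tRNA fragments were lowest in flower HMW relative to LMW (-2.67, adjusted p = 5.0e-07). Plastid reads were higher in HMW than unbound (leaf 1.13, adjusted p = 0.00121; flower 2.08, adjusted p = 4.2e-06), unlike most nuclear classes.

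The patterns taken up here were weighed against technical and biological sources. Tests of rRNA dilution were chosen after the result was seen, and those of the 23-nt share and the guides were fixed before their values were known. The first pattern is the low share of 24-nt reads starting with A in HMW, which dilution by rRNA fragments could produce in either tissue. In leaf, a difference of -1.59 remained outside structural RNA and organelles, so dilution is not the whole source. In flower, 0.0817 remained, which is what dilution alone would leave. With distinct sequences counted once the leaf difference shrank to -0.19, and the flower share turned to a call of higher in HMW (0.43). Against LMW the share outside structural RNA and organelles was lower in HMW of both tissues (-2.66 in leaf, -1.15 in flower).

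The second pattern is the large 23-nt share of the unbound pools. If 24-nt siRNAs had been shortened at the 3′ end during fractionation, the input should carry mostly 24-nt reads at the 5′ ends of unbound 23-nt reads. In the lowest of 4 libraries, 24-nt reads were 39.8% of the 23- and 24-nt input reads there, which leaves shortening possible. The same measure was higher for 23-nt reads of LMW in each tissue and replicate, at 49.4% and 50.0% in leaf and 51.8% and 55.9% in flower. It therefore does not set the unbound pool apart. Duplexes would give partners of 24 nt at an overlap of 21 or 22 nt. In the lowest library, these were 1.69 times as frequent as at overlaps of 1 to 15 nt. Partner rates rose with overlap, however, so this ratio mixes that rise with any pairing. That library was flower unbound replicate 1. There 17.3% of 23-nt reads had a partner at 22 nt, against 15.3% at 20 nt and 15.7% at 23 nt. In leaf unbound replicate 1 the rates were 28.8% at 22 nt and 22.9% at 23 nt. Leaf HMW, LMW and input had partners at 21 or 22 nt as well, at up to 3.61 times. In flower, input (1.54 and 1.58) and HMW (1.33 and 1.25) lay below unbound (1.69 and 1.83), while LMW (1.80 and 1.67) was near unbound. The peak of a flower unbound library was at 24 nt, so the part of pairing in the 23-nt share stays open.

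The third pattern is the spread of HMW versus unbound differences among leaf guides, from miR159a at 6.10 to miR157a-5p at -1.39. Length isoforms might mask enrichment of some guides, but summed isoforms kept 97.7% of the spread, even though single guides moved, such as miR167d from 3.86 to 0.14 and miR167a-5p from 1.497 to -1.81. Guides held with their star outside AGO complexes would give a negative correlation with the star to guide ratio of the input. The rank correlation was -0.22 across 21 hairpins (permutation p = 0.346), which neither supports nor rules out that source. Free miR156a-5p and miR168a-5p could also come from AGO complexes that fell apart on the column, which no measurement here tests.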
